A study of Mus musculus with 30 samples.

How the data were processed

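Gene expression was measured on 30 one-colour Affymetrix mouse arrays (MG-U74Av2) hybridized with biotin-labelled RNA from sorted CD4+ T cells. The cells came from NOD mice with the BDC2.5 T cell receptor transgene, whose T cells recognize a pancreatic islet antigen. Sorted cells were taken up in Trizol, and the labels of pancreas set 1 and of the lymph node set name 2 rounds of RNA amplification. Labels give an age of 26 days or 4 weeks where they give one. Nothing in the labels says that the replicates came from separate animals, so the p values measure the spread between these samples.

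The deposited file gave a linear intensity for each probe set and array, and log2 was taken before any test. The authors' processing notes name RMA, without a version, for the lymph node arrays and pancreas set 2, and the processing of pancreas set 1 is not given in the sources used here. The array medians were compared within each of the 3 sets of records. They spanned 0.0851 on the log2 scale in pancreas set 1, 0.0951 in pancreas set 2 and 0.0972 in the lymph node set. All 3 spans lay under the preset limit of 0.1, so these sets were used as deposited. Fits that joined sets were quantile-normalized together first. The number of arrays in each group limits the precision.

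The file held 12488 probe sets. The 66 Affymetrix control probe sets were left out of the tests, and the other 12422 were all tested. Of these, 10833 named 1 gene symbol, 396 named several and 1193 named none. The 8251 genes named alone were matched by Entrez identifier to the reference gene table (GRCm38.p6), and 8237 were found. The table served for gene names only, and no genome positions are given. The control probe sets of the lymph node arrays were stored in another order than those of the pancreatic arrays. Over the 66 controls, the mean values of the lymph node set and pancreas set 1 had r = 0.254 as stored and r = 0.952 after the names were reordered by letter case, against r = 0.984 over the other probe sets. These values are correlations across probe sets, which are not independent replicates. The reordered controls were used for the 3'/5' ratios of actin and Gapdh, which are given as log2 values throughout.

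Samples were grouped by tissue, sort and treatment as the titles give them. Pancreas set 1 held 3 arrays of Treg cells (CD4+CD25+CD69-) and 5 of Teff cells (CD4+, CD25 low or negative) from mice given rat IgG. Pancreas set 2 held 3 arrays of Treg cells (CD4+CD25+) and 3 of Teff cells (CD4+CD25-) from mice given antibody to ICOS, and 2 of IgG Treg cells. The gates of the IgG and anti-ICOS samples therefore differed. The lymph node set held 5 CD25+ and 3 CD25- arrays from mesenteric nodes and 3 of each from peripheral nodes. All peripheral arrays carried a mesenteric tissue entry against their titles and source names, and mesenteric CD25+ replicate 2 carried a CD25- source name against its title; the titles were followed. The array number of IgG Treg replicate 3 of set 1 appeared again as IgG Treg replicate 2 of set 2. Their profiles had r = 0.997 across probe sets, against at most 0.988 with any other pancreatic array, so this array was averaged and counted 1 time in joint fits. Array numbers in the labels fell into 5 runs, called A to E here, and the runs served as candidate batches.

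Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided). The Benjamini-Hochberg adjusted p was taken over 12422 probe sets, with a threshold of 0.05. Set 1, set 2 and the lymph node set were each fitted with all their groups. The comparison of anti-ICOS with IgG Teff cells and the interaction of treatment with cell type used a joint fit of 15 pancreatic arrays. The comparison of pancreas with lymph node used a joint fit of set 1 and the lymph node set. A log2 difference is the first group minus the second, given with its standard error (SE); group means are given with the SD. A gene was represented by its probe set with the highest mean, and other probe sets are quoted where they differed.

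Genes were named by a fixed rule. For each comparison it took the 10 genes with the largest positive and the 10 with the largest negative log2 difference among those past the threshold whose group values did not overlap, with no overlap condition for interactions. It also took the members of 24 gene lists, which held 370 genes, 296 of them with a probe set. Of list members past the threshold the results name a selection. The lists were Treg signature, costimulation and coinhibition, T cell cytokines, chemokine receptors, chemokines, naive and lymph node homing, T cell activation, Th1, Th2, Th17, cytotoxic, cell cycle, interferon response, apoptosis and survival, heat shock and isolation stress, T cell identity, and markers of B cells, macrophages and dendritic cells, granulocytes, CD8 and NK cells, exocrine pancreas, islet endocrine cells, stroma and endothelium, and erythroid cells. Lists were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the 24 lists. The grouping, comparisons, tests, lists, naming rule and the other settings to be tried were fixed before the data were examined.

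The procedure was tested on simulated data of 12422 probe sets, with 100 changed by log2 1 and 100 by log2 2. In the design of the pancreatic IgG comparison it recovered 90 % of changes of log2 1 and 100 % of changes of log2 2. For the anti-ICOS comparison of Treg with Teff these shares were 56 % and 91 %, and for anti-ICOS against IgG Teff cells 87 % and 100 %. For the interaction of treatment with cell type they were 63 % and 91 %. The changed probe sets were picked at random and the noise of each was drawn independently. These shares thus do not hold for genes in which an array departs from its group together, as anti-ICOS Treg replicate 3 did in Treg genes. In 50 simulated rounds, camera gave 4.67 % of unchanged lists an unadjusted p under 0.05. Genes were drawn independently of each other in these rounds, so the share says nothing about lists whose members vary together.

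Replicate numbers were checked as pairs by correlating, across probe sets, the deviations of same-numbered arrays from their group means. The anti-ICOS Treg and Teff arrays had r from 0.237 to 0.589 over 3 pairs, and 2 of the 3 were best matches, so a fit with replicate as a block was run beside the unblocked fit. RNA 3'/5' ratios were compared between groups with exact permutation tests. Those settings covered normalization, a filter on the dimmest 33.3 % of probe sets, limma's trend and robust options, an offset of 16, array-number run and replicate number as blocks, the choice of IgG arrays and the omission of each array. Settings with the actin 3'/5' ratio as covariate, without doubted arrays and within runs D and E, and the list tests with each array left out, were chosen after seeing the data. All per-sample columns of the file were used.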

Results

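The data comprised 30 arrays of sorted CD4+ T cells from BDC2.5 transgenic NOD mice, in which infiltrating T cells damage the islets. Pancreatic cells were sorted as regulatory (Treg) or effector (Teff) T cells from the infiltrated pancreas. Mice of pancreas set 1 had received control IgG (3 Treg and 5 Teff arrays). Pancreas set 2 held cells from mice given antibody to the costimulatory receptor ICOS (3 Treg and 3 Teff arrays) and 2 further IgG Treg arrays. CD25+ and CD25- cells of mesenteric nodes (5 and 3 arrays) and peripheral nodes (3 and 3 arrays) formed the lymph node set. Array medians ranged from 32.5 to 34.5 intensity units in set 1, from 27.9 to 29.8 in set 2 and from 25.3 to 27.1 in the lymph node set.

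The series title names the comparison of pancreatic Treg with Teff cells, tested here in IgG-treated mice of set 1. The genes with the largest rise in Treg cells were Klrg1, a receptor of differentiated T cells, and Socs2, a suppressor of cytokine signalling. Klrg1 was 9.40 ± 0.24 (log2 intensity, SD, n = 3) in Treg and 5.51 ± 0.18 (n = 5) in Teff cells, a log2 difference of 3.89 (SE 0.13, adjusted p = 2.58e-07) or 14.8-fold. Socs2 was 9.13 ± 0.07 against 5.30 ± 0.18, higher by 3.83 (SE 0.11, adjusted p = 1.07e-07). The protease granzyme B (Gzmb) rose by 3.67, the integrin Itgae by 3.28, S100a6 by 3.19, Lgals1 by 3.15, the costimulatory receptor Tnfrsf4 by 3.06, the decoy receptor Il1r2 by 2.88, Nrp1 by 2.65 and the transcription factor Ahr by 2.58. Lower in Treg cells were the coactivator Pou2af1 (-2.63, other probe set -0.25), Tdrp (-2.55, other probe set 0.02), Itm2a (-2.16), Nsg2 (-1.95), Smad1 (-1.94), Myb (-1.81, other probe set -0.16), Dusp6 (-1.75, other probe set -0.13), Smarca2 (-1.72) and Tbl1xr1 (-1.67). Ncl fell by 1.80 (adjusted p = 0.0332) and did not pass the test in 5 of the 8 fits that left out an array.

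Of 20 measured members of the Treg signature, 13 rose and 7 did not pass the test; 15 rose when adjusted over the list alone. The inhibitory receptor Ctla4 rose by 2.40 (SE 0.18, adjusted p = 4.79e-05), the suppressive cytokine Il10 by 2.30 (SE 0.19, adjusted p = 0.000117), the IL-2 receptor chain Il2ra by 2.00 (SE 0.22, adjusted p = 0.000676), Tnfrsf18 by 1.57 and the ectonucleotidase Entpd1 by 1.45. Il2ra encodes CD25, on which cells were sorted here and in the lymph nodes, so its rise is no independent finding. Foxp3 had no probe set. Icos differed by 0.61 (adjusted p = 0.0705). The list was higher by camera (adjusted p = 4.14e-21) and remained so with an estimated correlation (adjusted p = 0.00622).

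Of 26 cell cycle genes, 14 rose and 12 did not pass (17 rose and 1 fell when adjusted over the list alone). The proliferation marker Mki67 rose by 2.29 (SE 0.28, other probe set 0.17), Cdk1 by 1.47, Rrm2 by 1.47 and Ccnb2 by 1.35 (camera adjusted p = 1.95e-10; adjusted p = 0.234 with an estimated correlation). Of 12 cytotoxic genes, 7 rose, among them Gzmb, Gzmk by 1.15, Cst7 by 1.15 and Ctsw by 1.14, and 5 did not pass (7 rose and 1 fell when adjusted over the list alone; camera adjusted p = 3.98e-05, and adjusted p = 0.234 with an estimated correlation). Of 12 genes of naive cells and lymph node homing, 5 fell and 7 did not pass (6 fell when adjusted over the list alone). They included Actn1 (-1.63), the chromatin organizer Satb1 (-1.39) and the homing receptor Ccr7 (-0.77), with camera adjusted p = 3.98e-05 and adjusted p = 0.32 with an estimated correlation. In these same arrays the log2 3'/5' ratio of actin, a sign of RNA quality, averaged 3.75 in Treg and 2.65 in Teff cells (exact permutation test, two-sided, p = 0.0357 over 56 splits; p = 0.2 after adjustment over 8 such tests).

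Among 15 costimulation and coinhibition genes, 4 rose (Tnfrsf4, Ctla4, Tnfrsf18 and Pdcd1) and Cd28 fell (-1.38); adjusted over the list alone, 6 rose and 2 fell (camera adjusted p = 0.0289; adjusted p = 0.234 with an estimated correlation). Pdcd1 (0.58) did not pass without Treg replicate 2 or 3 or Teff replicate 2 or 5. Il10, the lymphotoxin gene Lta (1.00) and Csf1 (0.55) were the 3 of 15 T cell cytokines that rose, 3 also when adjusted over the list alone (camera adjusted p = 0.0189; adjusted p = 0.325 with an estimated correlation). Of 9 Th1 genes, 3 rose, including the chemokine receptor Cxcr3 (1.66) and Il18r1 (1.14), and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0294; adjusted p = 0.327 with an estimated correlation). Ahr and Ccr6 (0.83) rose among 5 Th17 genes, 2 also when adjusted over the list alone (camera adjusted p = 0.0425; adjusted p = 0.267 with an estimated correlation). Gbp3 (2.18), a guanylate-binding protein, and Igtp (0.90), Psmb9 (0.79) and Iigp1 (0.63) were the 4 of 22 interferon response genes that rose, 4 also when adjusted over the list alone (camera adjusted p = 0.0332; adjusted p = 0.361 with an estimated correlation). Cd2 (1.36), Cd5 (0.76) and Ptprcap (0.73) were among the 4 of 12 T cell identity genes that rose, 4 also when adjusted over the list alone (camera adjusted p = 0.0425; adjusted p = 0.413 with an estimated correlation). In the T cell activation list of 19 genes, Cd5 rose, the phosphatase Dusp2 (-0.68) and 1 further gene fell, and 2 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.0425, downward; adjusted p = 0.234 with an estimated correlation). Treg cells of set 1 were sorted as CD69- and Teff cells without a CD69 gate, so the activation call cannot be told apart from this gate. Without Treg replicate 3 all camera calls given in this paragraph but that of the cytokines were lost (adjusted p from 0.0788 to 0.199). Single arrays also ended the calls of Th1 genes (Treg replicate 1), Th17 genes (Teff replicate 1 or 4), interferon response genes (Teff replicate 1 or 2), T cell identity genes (Treg or Teff replicate 2) and activation genes (Treg replicate 2 or Teff replicate 3, 4 or 5), with adjusted p from 0.0505 to 0.0917, and the activation call was lost with the actin ratio as covariate, where its mean went from -0.18 to -0.16 (adjusted p = 0.0704).

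The other lists were not called by camera. Of 13 chemokine receptors, Ccr2 (1.73), Cxcr3 and Ccr6 rose and Ccr7 and 1 other fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.494). Ccl3 (0.66) was the 1 riser of 17 chemokines and Gata3 (0.71) the 1 of 9 Th2 genes, and both lists kept 1 when adjusted over the list alone. Of 16 apoptosis and survival genes, the kinase Pim1 (1.26) and Casp1 (0.76) rose and the proapoptotic gene Bcl2l11 (-0.70) fell (4 rose and 1 fell when adjusted over the list alone). Among 11 heat shock and isolation stress genes 1 fell, Dnajb1 (-0.56), which did not pass without Treg replicate 1 or 2 or Teff replicate 2 (2 fell when adjusted over the list alone). Of 16 B cell markers, Ighm (0.74, another probe set 1.48), Blk (0.58) and Cd79b (0.69, not past the test in 6 of the 8 fits that left out an array) rose and Pou2af1 fell, with 3 and 1 when adjusted over the list alone. Eomes (-1.18, other probe set -2.30) fell among 5 CD8 and NK cell markers, 1 also when adjusted over the list alone. By limma, no member passed among 16 macrophage and dendritic cell markers (1 at an unadjusted p under 0.05), 8 granulocyte markers (0 unadjusted), 11 exocrine pancreas markers (0 unadjusted), 9 islet endocrine markers (3 unadjusted, and 1 fell when adjusted over the list alone), 11 stroma and endothelium markers (2 unadjusted) and 4 erythroid markers (1 unadjusted, Hba-a1 with 1.17).

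In total 831 of 12422 probe sets passed the limma test, 488 higher and 343 lower in Treg cells, and 201 of them also exceeded a 2-fold change. Without Teff replicate 5 the count was 450, and without Treg replicate 2 it was 471. With the actin ratio as covariate 86 probe sets passed, 75 higher and 11 lower. Klrg1, Socs2, Gzmb, Itgae, Tnfrsf4, Nrp1, Ahr, Ctla4, Il10, Il2ra, Mki67, Cdk1, Ccnb2, Gzmk, Ctsw, Cxcr3, Ccr2, Gbp3, Tnfrsf18, Entpd1, Il18r1, Pou2af1, Tdrp, Itm2a, Nsg2 and Smad1 still passed in that fit. The other genes named above as rising or falling did not, among them S100a6 with 3.33, Il1r2 with 2.74, Dusp6 and Tbl1xr1 with -1.70 each, Rrm2 with 1.54 and Ccr7 with -0.81 in that fit. The named genes with the largest losses of size were Ptprcap (0.46), Lta (0.68), Ncl (-1.28), Iigp1 (0.46), Satb1 (-1.02), Smarca2 (-1.35), Myb (-1.46), Actn1 (-1.36), Cd79b (0.58) and Cd28 (-1.17). Lgals1 went from 3.15 to 2.88. Over 56 list and top genes whose call was lost, the difference kept a median of 102 % of its size (lowest 62.7 %), while the median SE went from 0.14 to 0.23.

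**Figure D1:**
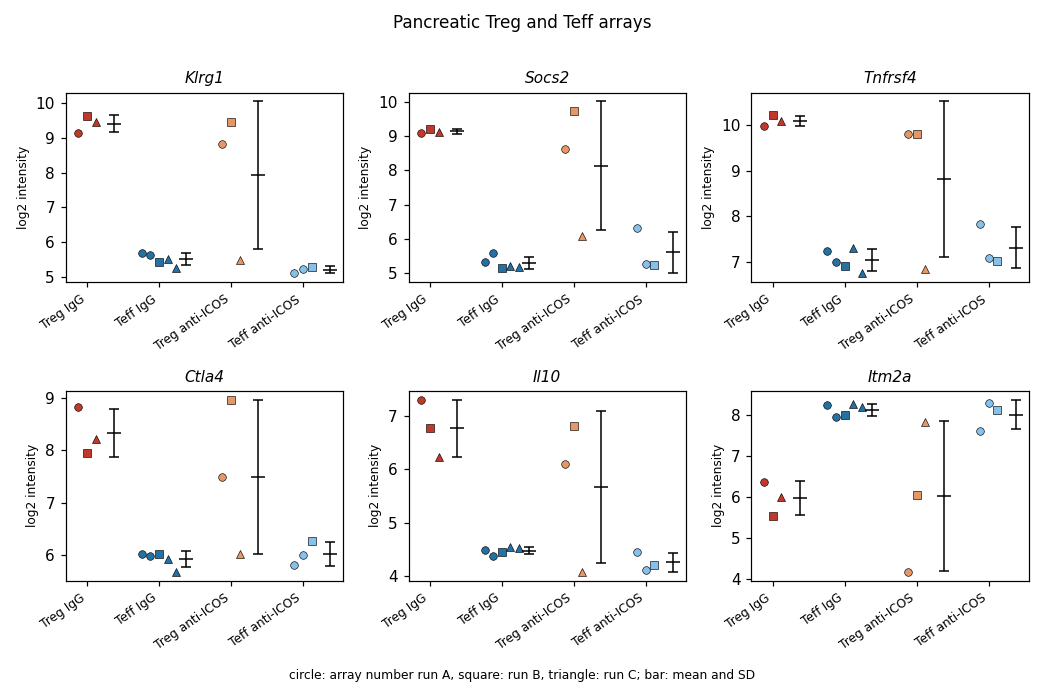
Log2 intensity of 6 genes on each array of 4 pancreatic groups, IgG Treg and Teff cells of set 1 and anti-ICOS Treg and Teff cells; circles, squares and triangles are array-number runs A, B and C, and bars give the mean and SD. Klrg1 lay between 9.13 and 9.61 in IgG Treg cells of set 1 and between 5.26 and 5.69 in IgG Teff cells, while anti-ICOS Treg replicate 3 had 5.50.

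The same sorts were compared in mice given antibody to ICOS. Klrg1 was 7.92 ± 2.12 (n = 3) in Treg and 5.22 ± 0.10 (n = 3) in Teff cells, a log2 difference of 2.70 (SE 0.86, adjusted p = 1). Socs2 differed by 2.53, Gzmb by 2.30, Il2ra by 1.53, Ctla4 by 1.47 and Il10 by 1.41. The gene for interferon gamma, Ifng, was 8.52 ± 1.43 in Treg and 6.60 ± 0.47 in Teff cells (1.92, SE 0.62). Treg replicate 3 stood apart in Klrg1, with 5.50 against 8.81 and 9.46 in replicates 1 and 2. It was also the lowest of the 3 for Itgae (3.41), Ctla4 (6.02) and Il2ra (3.88). Ifng was highest in replicate 1, with 10.11 against 8.13 and 7.33.

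No probe set passed the limma test, and 209 had an unadjusted p under 0.05; the fit with replicate as a block also gave 0 (864 unadjusted), and with array-number run as a block 15 passed, in a fit where Treg replicate 3 shared its run with no Teff array. Of the probe sets called in IgG-treated mice, 98.2 % had the same sign here, and the contrasts had r = 0.73 across probe sets, or 0.78 without replicate 3 and 0.44 without Treg replicate 1. Without Treg replicate 3, 12 probe sets passed, among them Klrg1 (3.91), Socs2 (3.56), Il1r2 (3.49), the opioid precursor Penk (3.10), Tnfrsf4 (2.49), Il10 (2.20), Tnfrsf1b (1.99), Ighm (1.82), Tnfrsf18 (1.47) and Tdrp (-2.67), all with the same sign and past the test in IgG-treated mice. As a list, the Treg signature was higher (17 of 20 members positive, camera adjusted p = 3.16e-12; adjusted p = 0.527 with an estimated correlation), as was the cell cycle list (25 of 26 positive, adjusted p = 1.79e-09; adjusted p = 0.552 with an estimated correlation). Cytotoxic genes (camera adjusted p = 0.00527), Th17 genes (0.0426) and, downward, naive and homing genes (0.0109) were also called, with adjusted p = 0.552, adjusted p = 0.527 and adjusted p = 0.552 with an estimated correlation. None of these lists had a member past the test, and none when adjusted over the list alone. The camera calls of cytotoxic and of naive and homing genes were lost without Treg replicate 1 (adjusted p = 0.114 and 0.851) or Teff replicate 3 (0.066 and 0.145). That of Th17 genes was lost without Treg replicate 2, Teff replicate 1 or 2 or either IgG array (from 0.0663 to 0.249), and all 3 were lost with the actin ratio as covariate (0.602, 0.973 and 0.0607). With it the mean of cytotoxic genes went from 0.49 to 0.24, of naive and homing genes from -0.25 to -0.03 and of Th17 genes from 0.50 to 0.53. The log2 actin 3'/5' ratio averaged 3.05 in Treg and 2.29 in Teff cells (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows, and 0.2 adjusted).

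Anti-ICOS and IgG treatment were compared within Treg cells of set 2. Ifng showed the smallest unadjusted p among list genes, with 10.11, 8.13 and 7.33 in the anti-ICOS arrays and 5.37 and 5.59 in the IgG arrays, a log2 difference of 3.04 (SE 0.69, adjusted p = 0.893). It was the only gene past the threshold when adjusted over the list alone, for the cytokine list and for the Th1 list (1 each). Both rest on the same p value, with no adjustment over the lists. As deposited, IgG Treg arrays of set 1 reached higher Ifng values than the IgG arrays used here. IgG replicate 1 came from array-number run E, which held no anti-ICOS array. The immediate early gene Fos differed by 1.88 and the granzyme Gzma by 1.48. Lysozyme (Lyz2) and alpha globin (Hba-a1), markers of myeloid and red cells, differed by -3.32 and -3.17. In IgG replicate 1 of set 2 they stood at 9.12 and 13.21, against 3.37 and 11.43 in IgG replicate 2.

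No probe set passed the limma test (425 unadjusted), and 35 passed without IgG replicate 2, which leaves a lone IgG array assumed to vary like the other groups. By camera, T cell activation genes were higher after anti-ICOS (adjusted p = 0.00323; adjusted p = 0.296 with an estimated correlation), also in each of the 8 fits that left out an array. Heat shock genes were higher over all arrays (0.00505; adjusted p = 0.296 with an estimated correlation), with a list mean of 6.33 in IgG replicate 1, 7.01 in IgG replicate 2 and 7.07 to 7.20 in the anti-ICOS arrays. Without IgG replicate 1 their mean difference went from 0.45 to 0.11 and the call was lost (adjusted p = 0.122), as it was without anti-ICOS replicate 1 (0.0729). The Treg signature was lower over all arrays (0.00973; adjusted p = 0.704 with an estimated correlation), with a list mean of 6.12, 6.62 and 4.90 in the anti-ICOS arrays and of 6.31 and 6.49 in the IgG arrays. Without anti-ICOS replicate 3, the array with Klrg1 at 5.50, its mean difference went from -0.52 to -0.03 and the call was lost (adjusted p = 0.792), as it was without IgG replicate 2 (0.23). Macrophage and dendritic cell markers (0.0145; adjusted p = 0.704 with an estimated correlation) and erythroid markers (0.0131; adjusted p = 0.704 with an estimated correlation) were lower over all arrays. Both calls were lost without IgG replicate 1, with mean differences of 0.11 and -0.87 (adjusted p = 0.258 and 0.316), and without anti-ICOS replicate 1 (0.0729 each), and the first also without anti-ICOS replicate 2 (0.104). With the actin ratio as covariate both were lost too (0.19 and 0.0567), as the means went from -0.50 to -0.30 and from -1.53 to -1.22. The gates also differed, since the IgG Treg cells were sorted as CD69-.

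Teff cells of anti-ICOS and IgG-treated mice were compared in the joint pancreatic fit, where treatment and set coincide. Interferon response genes were higher after anti-ICOS as a list, with 21 of 22 members positive and a median of 0.22 (camera adjusted p = 3.32e-08; adjusted p = 0.00788 with an estimated correlation). Their values included Gbp2 with 0.57, Iigp1 with 0.50, Igtp with 0.38 and Isg15 with 0.28. Ifng itself was 6.65 ± 0.51 (n = 3) against 5.15 ± 0.58 (n = 5), without passing the test (SE of the difference 0.55, adjusted p = 0.999). The NK receptor gene Klrk1 differed by 0.60 and Gzma by 1.12.

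No probe set passed the limma test (512 unadjusted); 1 passed without IgG Treg replicate 1 of set 1 and 1 with limma's trend and robust options. Without joint normalization 4390 passed, 4387 of them lower in set 2, whose medians were lower. Cytotoxic (camera adjusted p = 5.98e-05; adjusted p = 0.196 with an estimated correlation), cell cycle (0.000889; adjusted p = 0.78 with an estimated correlation), Th1 (0.0182; adjusted p = 0.371 with an estimated correlation), CD8 and NK (0.0187; adjusted p = 0.16 with an estimated correlation) and cytokine genes (0.0234; adjusted p = 0.382 with an estimated correlation) were higher as lists. Without anti-ICOS Teff replicate 1 the camera calls of cytotoxic, cell cycle, Th1 and cytokine genes were lost (adjusted p = 0.0848, 0.0848, 0.746 and 0.437). The Th1 call was also lost without IgG Teff replicate 3 (0.117), the cytokine call without IgG Teff replicate 3 or 5 or anti-ICOS Teff replicate 3 (from 0.0514 to 0.119), and the CD8 and NK call without anti-ICOS Teff replicate 2 or 3 (0.127 and 0.112). When adjusted over the list alone, 2 CD8 and NK genes, 1 cytotoxic gene and 1 chemokine passed.

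The difference of the anti-ICOS effect between Treg and Teff cells was tested as an interaction. The sort gates coincided with treatment and do not cancel in it. IgG Treg cells were sorted as CD69-, a gate not given for anti-ICOS Treg cells or for Teff cells. An effect of treatment cannot be told apart from this gate. No probe set passed the limma test (327 unadjusted), and Ifng differed by 0.97 (SE 0.79, adjusted p = 1). The Treg signature was lower as a list (camera adjusted p = 2.63e-06; adjusted p = 0.325 with an estimated correlation), and heat shock genes were higher (0.000588; adjusted p = 0.0636 with an estimated correlation). Erythroid (0.00732), interferon response (0.0268), macrophage and dendritic cell (0.0268), granulocyte (0.0363) and exocrine (0.0358) genes were lower and naive and homing (0.0268) and T cell activation genes (0.0363) higher, each with adjusted p = 0.325 or adjusted p = 0.473 with an estimated correlation. Anti-ICOS Treg replicate 3, with Klrg1 at 5.50, was part of this contrast, and the count was also 0 without it. The mean of the Treg signature went from -0.68 to -0.22 without this array, still called, and the calls of naive and homing, activation and granulocyte genes were lost without it (adjusted p = 0.59, 0.249 and 0.0903). Leaving out each of the 15 arrays in turn ended the calls of interferon response, macrophage and dendritic cell, granulocyte, exocrine, naive and homing, and activation genes in 6, 5, 10, 8, 6 and 8 fits, and those of heat shock and erythroid genes without anti-ICOS Treg replicate 1 (0.0507 and 0.058). With the actin ratio as covariate the calls of macrophage and dendritic cell, granulocyte, exocrine, naive and homing, and activation genes were lost (from 0.0656 to 0.18). Their means went from -0.35 to -0.28, -0.21 to -0.14, -0.30 to -0.23, 0.26 to 0.20 and 0.16 to 0.15.

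In mesenteric lymph nodes the gene with the largest rise in CD25+ over CD25- cells was Trgv1, a T cell receptor gamma gene segment. It was 10.01 ± 0.10 (n = 5) in CD25+ and 5.56 ± 0.23 (n = 3) in CD25- cells, higher by 4.45 (SE 0.13, adjusted p = 1.27e-10). The membrane protein genes Tmem176a and Tmem176b rose by 4.08 and 4.07, Socs2 by 3.69, Nrp1 by 3.64, the chemokine receptor Ccr6 by 3.02, S100a6 by 2.99, Ctla4 by 2.98, Klrg1 by 2.66 and the lectin receptor Klrb1b by 2.62. Lower in CD25+ cells were Tdrp (-2.98, other probe set 0.09), Bzw1 (-2.88), Rrs1 (-2.31), beta catenin (Ctnnb1, -2.26), Atp6ap2 (-2.24), Tspyl4 (-2.22), the kinase Sgk1 (-2.18), Ubqln1 (-2.17, other probe set -0.28), Mfsd14b (-2.16) and Dusp6 (-2.11, other probe set -0.15).

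Of 20 Treg signature members 14 rose (16 when adjusted over the list alone), including Ctla4, Tnfrsf4 by 2.53, Gpr83 by 2.12 and Il2ra by 1.57 (camera adjusted p = 4.26e-13; adjusted p = 0.00106 with an estimated correlation). Of 15 costimulation genes 4 rose, 5 when adjusted over the list alone (adjusted p = 0.00739; adjusted p = 0.0556 with an estimated correlation). Ccr6 and Ahr (1.78) rose among 5 Th17 genes, 4 when adjusted over the list alone (adjusted p = 0.00739; adjusted p = 0.171 with an estimated correlation). Of 12 naive and homing genes 4 fell, including Satb1 (-1.19), and 1 rose; adjusted over the list alone, 5 fell and 1 rose (adjusted p = 0.039; adjusted p = 0.177 with an estimated correlation). The last of these calls was lost without CD25- replicate 2, CD25+ replicate 2 or 3 or peripheral CD25+ replicate 1 (adjusted p from 0.0515 to 0.0778), and with the actin ratio as covariate (0.0607, as its mean went from -0.23 to -0.21). The mean of 16 B cell markers was also higher in these CD25+ arrays, at 5.55 to 5.93 against 5.03 to 5.32 in CD25- arrays, and replicate 4 had the highest value both of these markers and of Ccr6 (10.56). Gzmb rose by 2.51 and the lymphotoxin gene Lta by 1.92, in lists that camera did not call.

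In all, 1514 probe sets passed the limma test, 579 higher and 935 lower, with 3083 unadjusted. Without CD25- replicate 1 the count was 798, and without CD25- replicate 2 it was 743. Within run D (2 arrays against 2) it was 548, and within run E (3 against 1) it was 108. The log2 actin ratio averaged 2.85 in CD25+ and 2.63 in CD25- cells (exact permutation test, two-sided, p = 0.0714, and 0.2 adjusted).

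In peripheral lymph nodes Trgv1 was 9.33 ± 0.23 (n = 3) in CD25+ and 5.33 ± 0.20 (n = 3) in CD25- cells, higher by 4.00 (SE 0.14, adjusted p = 2.45e-09). Socs2 rose by 3.94, Klrg1 by 3.42, Nrp1 by 3.30, S100a6 by 3.26, Lgals1 by 2.89, Gzmb by 2.80, Tmem176b by 2.51, Crip1 by 2.43 and Itih5 by 2.35 (other probe set -0.11). The ribosome biogenesis gene Rrs1 (-2.76), Bzw1 (-2.60), Tdrp (-2.46, other probe set 0.23), Dusp6 (-2.28, other probe set 0.05), Ctnnb1 (-2.20), Ugcg (-2.14), Atp6ap2 (-2.06), Ubqln1 (-2.05), the chaperonin subunit Cct8 (-2.04) and Tmem68 (-1.99) fell. Crip1 and Atp6ap2 did not pass in 4 and 2 of the 14 fits that left out an array. They did not pass with the actin ratio as covariate either (adjusted p = 0.176 and 0.11). Neither was smaller there, and the SE went from 0.58 to 0.84 and from 0.45 to 0.65. Of 20 Treg signature members 11 rose (13 when adjusted over the list alone), with Ctla4 at 1.40 and Il2ra at 1.35 (camera adjusted p = 4.68e-13; adjusted p = 0.00107 with an estimated correlation). Of 11 heat shock genes 4 fell, 4 also when adjusted over the list alone, among them the mitochondrial chaperones Hspd1 (-1.02) and Hspe1 (-0.95) (adjusted p = 0.0141; adjusted p = 0.307 with an estimated correlation). This camera call was lost without CD25- replicate 3 (adjusted p = 0.12), without CD25+ replicate 1 (0.0715) and with the actin ratio as covariate (0.202, as its mean went from -0.44 to -0.27). With that covariate Hspd1 had -0.61 and Hspe1 -0.72 (adjusted p = 0.089 and 0.0611), and neither these nor Gzmb (2.43), Lgals1 (2.28) and Ubqln1 (-1.83) passed (0.0677, 0.2 and 0.0735). The activation genes Egr2 (-1.55) and Irf4 (-1.46) also fell, in a list of 19 that camera did not call (2 fell; adjusted over the list alone, 2 rose and 5 fell).

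In these nodes 955 probe sets passed the limma test, 223 higher and 732 lower, with 2585 unadjusted. The count was 1462 without CD25+ replicate 1, 531 without CD25+ replicate 2, 546 without CD25- replicate 2 and 597 without CD25- replicate 3. It was 446 within run D (2 arrays against 2), 513 with these groups fitted alone and 267 with the actin ratio as covariate. The log2 actin ratio averaged 3.02 in CD25+ and 2.54 in CD25- cells (exact permutation test, two-sided, p = 0.1, the smallest allowed, and 0.2 adjusted).

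Mesenteric and peripheral cells were compared next, first among CD25- cells. Interferon response genes were higher in mesenteric cells: Ifit3 was 7.33 ± 0.61 (n = 3) against 4.17 ± 0.31 (n = 3), higher by 3.16, and Ifit1 was higher by 3.15 (SE 0.30, adjusted p = 0.000154). Usp18 was higher by 2.91, Cmpk2 by 2.47 (other probe set 0.65), Mx1 by 2.00, Rsad2 by 1.93, Isg15 by 1.92, the RNA sensor Ifih1 by 1.85, Gm9706 by 1.76 and Socs3 by 1.65. Lower in mesenteric cells were Myb (-2.26, other probe set -0.03), Ctla4 at 3.96 ± 0.17 against 5.67 ± 0.32 (-1.71, SE 0.17, adjusted p = 0.000249), the T-box factor Eomes (-1.63; its other probe set was at background in mesenteric cells), Irf4 (-1.61), Irf8 (-1.51), Hmgb3 (-1.29), the cytokine gene Tnfsf11 (-1.29), Cd200 (-1.29), Nr4a1 (-1.16) and the checkpoint kinase Chek1 (-1.06). Of the 14 fits that left out an array, Rsad2, Tnfsf11, Cd200, Nr4a1 and Chek1 did not pass in 1, 4, 3, 4 and 7. Nr4a1 (-1.15) and Chek1 (-1.06) did not pass with the actin ratio as covariate either (adjusted p = 0.0534 and 0.0547).

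Of 22 interferon response genes 8 were higher, and 14 when adjusted over the list alone (camera adjusted p = 1.74e-33; adjusted p = 0.011 with an estimated correlation). Of 19 T cell activation genes 3 were lower, and 5 when adjusted over the list alone (adjusted p = 9.49e-08; adjusted p = 0.011 with an estimated correlation). Ctla4 was among the 3 of 15 costimulation genes that were lower, 3 also when adjusted over the list alone (adjusted p = 0.000407; adjusted p = 0.011 with an estimated correlation). Naive and homing genes were higher as a list of 12, with 3 past the threshold when adjusted over the list alone (adjusted p = 5.62e-06; adjusted p = 0.011 with an estimated correlation). Cell cycle genes were lower as a list, with 25 of 26 negative (adjusted p = 1.17e-09; adjusted p = 0.0684 with an estimated correlation). Altogether 56 probe sets passed the limma test, 26 higher and 30 lower, with 522 unadjusted. The count was 36 without peripheral CD25- replicate 2, 28 within run D and 0 within run E, where 1 array stood against 1 (844 unadjusted).

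Among CD25+ cells, Ifit1 was 7.46 ± 0.24 (n = 5) in mesenteric and 4.93 ± 0.79 (n = 3) in peripheral nodes, higher by 2.53 (SE 0.27, adjusted p = 0.00272). Ifit3 was higher by 2.45, Usp18 by 2.02, Isg15 by 1.83, Mx1 by 1.62, Gm9706 by 1.61 and Ifih1 by 1.29. Of 22 interferon response genes 5 were higher, and 12 when adjusted over the list alone (camera adjusted p = 4.04e-18; adjusted p = 0.0901 with an estimated correlation). Th17 genes were higher as a list, with 2 past the threshold when adjusted over the list alone (adjusted p = 0.000399; adjusted p = 0.0901 with an estimated correlation). Cell cycle genes were lower, with 26 of 26 negative (adjusted p = 1.26e-07; adjusted p = 0.154 with an estimated correlation), as were cytotoxic genes (adjusted p = 0.0307; adjusted p = 0.154 with an estimated correlation). Both of these calls were lost without peripheral CD25+ replicate 3 (adjusted p = 0.0617 and 0.884), and the second also without mesenteric CD25+ replicate 1 (0.0719). Only 9 probe sets passed the limma test, 7 higher and 2 lower, with 532 unadjusted. The count was 2 without peripheral CD25+ replicate 2, 5 without replicate 1 and 21 without replicate 3. Among the 14 fits that left out an array, Ifit3 failed without peripheral replicate 2, Isg15 and Gm9706 failed without peripheral replicate 1 or 2, and Usp18 and Mx1 failed in 10 and 9. None of the gene calls remained with replicate number as a block and both groups fitted alone. With the actin ratio as covariate the count was 5, and Usp18, Gm9706 and Mx1 did not pass (adjusted p = 0.127, 0.0821 and 0.194), though each kept at least 92.7 % of its size (median SE 0.26 without and 0.28 with it). Within run E, with 3 arrays against 1, it was 0 (393 unadjusted), and the mean of the interferon list was 0.26, against 0.93 within run D and 0.71 over both.

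**Figure D2:**
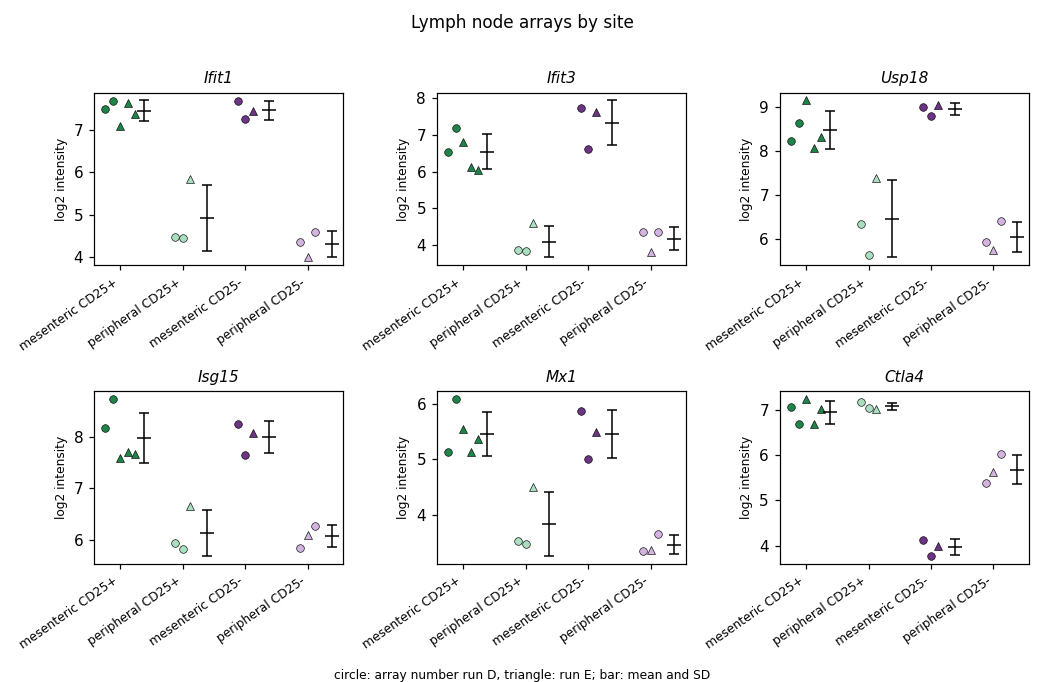
Log2 intensity of 6 genes on each lymph node array, by site and sort; circles are array-number run D, triangles run E, and bars give the mean and SD. Ifit1 averaged 7.46 in mesenteric cells of either sort, 4.93 in peripheral CD25+ and 4.32 in peripheral CD25- cells.

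The contrast of regulatory with other CD4+ cells was compared between pancreas and lymph nodes. Across 12422 probe sets the pancreatic IgG contrast had Pearson r = 0.58 (Spearman 0.42) with the mesenteric and r = 0.63 (Spearman 0.41) with the peripheral contrast, and the lymph node contrasts had r = 0.86 (Spearman 0.66) with each other. Probe sets are not independent replicates. The mean log2 actin ratio was higher in Treg or CD25+ cells in each contrast. It was 3.75 against 2.65 in pancreatic IgG, 2.85 against 2.63 in mesenteric and 3.02 against 2.54 in peripheral cells. The Gapdh ratio went the other way in peripheral cells (3.38 against 3.50). The part of RNA quality in these correlations and in the shared calls was not tested. The pancreatic and mesenteric contrasts shared 180 rising and 166 falling calls, where chance would give 22.7 and 25.8, and 6 calls had opposite signs. Pancreas and peripheral nodes shared 120 and 161, against 8.76 and 20.2 by chance, with 2 opposite. The anti-ICOS contrast had r = 0.54 with the mesenteric and r = 0.59 with the peripheral contrast, and both were 0.18 without Treg replicate 1.

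In this comparison of pancreas with lymph nodes, tissue coincided with the set of records and with the sort gates. A constant offset between sets cancels in the interaction. A difference in scale or gate does not, and it cannot be told apart from tissue. Tested as an interaction, Il10 had a larger Treg rise in the pancreas, by 1.90 (SE 0.26, adjusted p = 0.000653). So did Il1r2 by 2.32 (SE 0.37, adjusted p = 0.00255), Fam3c by 2.20 (other probe sets 0.32 and 0.14), Itgae by 2.06, the topoisomerase Top2a by 1.98, Gbp3 by 1.72, Slbp by 1.62, Sh3bgrl by 1.61, Kpna2 by 1.60 and Rrm2 by 1.58. The contrast was lower in the pancreas for Klf3 (-2.80, SE 0.50, adjusted p = 0.00578, other probe set -0.26), Tmem176b (-2.71), Tmem176a (-2.10), Trgv1 (-2.03, adjusted p = 1.04e-06), the corepressor Nrip1 (-1.86), Lmo4 (-1.83), Cd28 (-1.81), Gpr83 (-1.79), Klrb1b (-1.74), Tcf4 (-1.74), the receptor chain Il6ra (-1.66) and Ccr6 (-1.63). Of the 22 fits that left out an array, Sh3bgrl, Nrip1, Cd28 and Tcf4 did not pass in 9, 15, 1 and 2. With the actin ratio as covariate they had 1.31, -1.83, -1.64 and -1.46. None of the 4 passed there (adjusted p from 0.156 to 0.251).

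Of 26 cell cycle genes 5 were higher in this comparison, and 13 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.13e-08; adjusted p = 0.245 with an estimated correlation). Of 12 naive and homing genes 3 were lower, 3 also when adjusted over the list alone (adjusted p = 0.0103; adjusted p = 0.245 with an estimated correlation), and cytotoxic genes were higher (adjusted p = 0.0429; adjusted p = 0.311 with an estimated correlation). The naive and homing call was lost without Treg replicate 2 (adjusted p = 0.0593) or Teff replicate 3 (0.072), and the cytotoxic call in 11 of the 22 fits that left out an array (from 0.0528 to 0.287) and with the actin ratio as covariate (0.0619, as its mean went from 0.30 to 0.27). The Treg signature, with 3 higher and 1 lower of 20, was not called (adjusted p = 0.0709). In all 258 probe sets passed the limma test, 152 higher and 106 lower, with 1763 unadjusted; the count was 160 without Teff replicate 5 and 449 without peripheral CD25+ replicate 1. It was 52 against the peripheral contrast alone, 56 with the actin ratio as covariate, where Gbp3 (1.66, SE 0.35 without and 0.41 with it, adjusted p = 0.0785) and Rrm2 (1.54, SE 0.29 and 0.34, adjusted p = 0.0508) did not pass, and 4 with the anti-ICOS contrast in place of IgG.

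**Figure D3:**
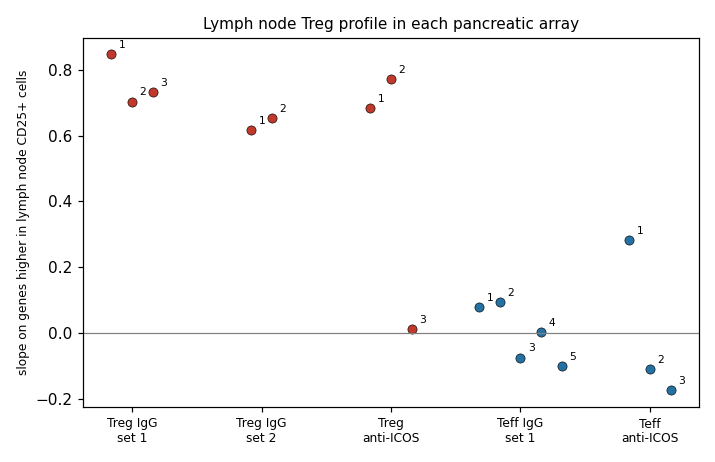
Slope of each pancreatic array, relative to the Teff mean of its set, on the log2 differences of genes higher in lymph node CD25+ cells; points carry replicate numbers. Treg arrays lay between 0.617 and 0.847 except anti-ICOS replicate 3 with 0.0116, and Teff arrays between -0.174 and 0.283.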

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

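The tests of the 3 patterns weighed here, and the test of site against CD25, were chosen only after the results were seen, while the splits of the samples and the search for arrays far from their group were set beforehand.

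In groups of 4 to 10 arrays, 92 measures were searched for an array far from the others, and 4 were found, where chance gives about 1 in 20 groups or 4.6. Mesenteric CD25+ replicate 4 had a mean of 5.08 (log2) over macrophage and dendritic cell markers, against 4.95 to 4.98 in the other arrays of its group. Its Ccr6 was 10.56, against 9.31 to 9.55 in the others. Trgv1 was 10.19 in mesenteric CD25+ replicate 5, against 9.93 to 10.001. Pancreatic IgG Teff replicate 5 had a mean of 7.27 over heat shock and isolation stress genes, against 7.14 to 7.17.

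The Treg contrast differed between pancreas and lymph nodes, where tissue coincided with the set of records and the sort gates. By a test of the difference itself, this held for 258 probe sets. Among them Il1r2 differed by 2.32 and Klf3 by -2.80, whose other probe set had -0.26. The CD25 contrast differed between mesenteric and peripheral nodes for 1 probe set, with 382 at an unadjusted p under 0.05 by limma. It belonged to the T-box factor Eomes, with a fitted difference of 2.32 (adjusted p = 1.93e-06). Its means were 3.16 in peripheral CD25+ and 5.58 in peripheral CD25- cells, but 2.48 and 2.58 in mesenteric CD25+ and CD25- cells, at or below the 5th percentile of the mesenteric arrays (log2 2.58 to 2.67). The probe set was thus at background in both mesenteric sorts, so a contrast below background could not be seen there. It cannot tell a different CD25 contrast from a low Eomes level in mesenteric cells, and it does not show that the contrast differs between the sites. Another Eomes probe set, at 4.02 and 4.01 in mesenteric cells, gave 1.26 in the same direction (limma unadjusted p = 0.000182, adjusted p = 0.322).

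Other splits of the same arrays into groups of the same sizes were fitted for counts that compared groups directly, except anti-ICOS against IgG Treg cells. For the interaction of treatment with cell type, treatment labels were drawn anew within each cell type. For pancreatic IgG Treg against Teff, 1 of 56 splits, the real one, gave as many calls (831, highest other 1). For the mesenteric CD25 contrast it was again 1 of 56 (1514, highest other 140). Chance is thus unlikely for both, at a share under 0.05, but so few splits cannot exclude it. For the pancreas against lymph node contrast, residuals of a fit without the difference were shuffled over arrays in place of splits. Of 100 counts, the real one included, 2 were at least the real 258, and the highest other was 279. Chance alone thus reached this count, so it is unlikely at a share under 0.05 but not excluded. With 10 splits each, the peripheral CD25 contrast (955, highest other 126, with 1 split as large) and the site contrast in CD25- cells (56, highest other 2, with 1 as large) have too few splits for a share under 0.05.

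Where the real count was 0 by limma, every split gave at least as many, so the splits say nothing about chance. This holds for anti-ICOS Treg against Teff cells (209 unadjusted; 10 of 10 splits, highest other 0, with 0 also in the 4 that part all 3 pairs of same-numbered arrays). It also holds for anti-ICOS against IgG Teff cells (512 unadjusted; 56 of 56, highest other 1) and for the interaction of treatment with cell type (327 unadjusted; 100 of 100 draws). In the interaction the highest other count of 2535 points to a structure of the samples. That draw parted the Treg arrays by their log2 actin ratio, 2.45 to 3.02 against 3.69 to 4.53. A draw with 567 calls did not part them fully. In the first draw the Teff arrays labelled anti-ICOS were all of run A, though anti-ICOS Teff replicate 2 of that run was not among them. The part of the ratio or the run in these counts was not tested. Chance cannot be excluded for the site contrast in CD25+ cells, where 3 of 56 splits gave at least 9 calls. The other 2 of them gave 541 each, which also points to a structure of the samples: each followed array-number runs D and E except for 1 array. With the runs as a block the real split gave 11 calls, within run D 8 and within run E 0.

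The array labelled anti-ICOS Treg replicate 3 lacked the Treg profile, with a slope of 0.0116 on genes higher in lymph node CD25+ cells. A swap with a pancreatic Teff array was argued against, since on these genes the highest Teff slope was 0.283, below the lowest other Treg slope of 0.617; on falling genes the sorts overlapped, with 0.65 in anti-ICOS Teff replicate 1 and 0.0958 in anti-ICOS Treg replicate 2. A loss of the rising genes shared by all anti-ICOS Treg cells was argued against by the lower of the other slopes, 0.684, within the IgG Treg range of 0.617 to 0.847, but for falling genes a loss stays open, since replicate 2 lay below and replicate 1 (1.01) within the IgG range of 0.329 to 1.11. Teff cells, or another Teff array, under this label stay open: on 64 pancreatic calls not called in lymph nodes its slope was -0.0808, within the anti-ICOS Teff range of -0.203 to 0.302 and far from 0.811 and 0.926 in the other anti-ICOS Treg arrays. The IgG Treg arrays of set 2 had 0.481 (replicate 1) and 0.900 (replicate 2, the array shared with set 1). A loss of the profile in the cells of this sample alone was not tested.

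The IgG Treg and Teff arrays of the pancreas differed in the log2 actin 3'/5' ratio, 3.75 against 2.65. In the joint pancreatic fit, the 13 risers of the Treg signature had a median difference of 2.37 without and 2.34 with the ratio as covariate (median SE 0.38 and 0.53), and 10 of the 13 passed with it in set 1, which argues against the ratio as their whole cause. The 343 falling calls went from a median of -0.82 to -0.50 (SE 0.21 and 0.26), and the 472 rising calls outside the signature from 0.69 to 0.56 (SE 0.20 and 0.26), which leaves out 3 second probe sets of signature genes. The joint count went from 502 to 0, as the covariate widened the errors and took part of the difference; in set 1 alone the falling median went from -0.72 to -0.66 (SE 0.15 and 0.24) and the other rising one from 0.71 to 0.74 (SE 0.13 and 0.20), and 10 and 62 of these calls passed, so there they ended mainly as errors widened. For these calls the ratio and the cell type cannot be told apart, since the ratio itself followed the sort, and a real difference between the cells stays open.

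Interferon response genes were higher in mesenteric than in peripheral nodes. In CD25- cells the array-number run was argued against by the lowest within-run mean of 1.03, beside 1.07 over both runs, and the RNA 3'/5' ratio by a mean of 1.10 with it as covariate. In CD25+ cells the mean within run D was 0.93 (2 arrays against 2, 19 of 22 genes positive), which argues against run as the whole cause in those arrays. The lowest within-run mean was 0.26, from run E with 1 peripheral array, against 0.71 over both runs. How far the size of the difference depends on run thus cannot be told there. Other cells were argued against in the mesenteric CD25- sorts only, since B cell markers had a median of -0.0311 and macrophage and dendritic cell markers 0.00641 beside 0.66 for the interferon list; their abundant Ctss and Ighm differed by 0.30 and 0.06, 11 of the B cell and 7 of the other markers lay above the array median in peripheral CD25- cells, and the sort was gated on CD4, with its purity untested. In CD25+ sorts other cells stay open, since 5 of 19 such markers above the array median differed by at least the 0.37 of the interferon list, all of the B cell list and among them H2-Aa with 1.15 (SE 0.47), while Ms4a1 had -0.62 (SE 0.46), Ighm -0.29 (SE 0.28) and the 8 macrophage and dendritic cell markers -0.12 to 0.10; a difference in the biology of the sites stays open as a hypothesis, untested, and the peripheral arrays also carry a mesenteric tissue entry.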

How the results depend on the processing

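Settings with the actin 3'/5' ratio as covariate, without doubted arrays and within runs D or E, and the list tests with arrays left out, were chosen only after the results were seen. Among named genes past the test in the main fit, none turned its direction under any setting. No called list turned its direction and passed the test with an array left out. Comparisons without a call in the main fit had no such genes, so gene directions were not followed there. Of 2011 gene values under the settings set beforehand, 1784 kept their side of the threshold and 227 lost it; with an array left out, 441 of 3772 lost it. Counts that moved by over 1.5 times follow, and the cause was not tested except where fewer arrays were fitted. Near background, leaving out the dimmest 33.3 % of probe sets moved no count that far.

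With the actin ratio as covariate, counts were 86 for pancreatic IgG Treg against Teff, 267 for the peripheral CD25 contrast, 5 for the site contrast in CD25+ cells and 56 for pancreas against lymph node. Without arrays of a log2 actin ratio above 4 the first was 471. With array-number run as a block, 15 passed for anti-ICOS Treg against Teff, where Treg replicate 3 shares run C with no Teff array, so that replicates 1 and 2 alone carry the contrast. The 3 that passed for anti-ICOS against IgG Treg say little, since only run C holds both arms, with anti-ICOS replicate 3 against IgG replicate 2. Without joint normalization 4390 passed for anti-ICOS against IgG Teff, and with trend and robust 1. Within runs D and E, the mesenteric contrast gave 548 and 108, the peripheral 446 and 241, and the site contrast in CD25- cells 28 and 0 (844 unadjusted in limma); in CD25+ cells run E gave 0 (393 unadjusted). Run E held 3 mesenteric CD25+ arrays and 1 of each other lymph node group, so its 241 and 844 compare 1 array with 1, and the spread in all its fits came from those 3 arrays.

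Replicate numbers as a block gave 0 (864 unadjusted) for anti-ICOS Treg against Teff, 1542 for the mesenteric and 563 for the peripheral contrast, and 0 (654 unadjusted) and 79 for the site contrasts in CD25+ and CD25- cells. In the CD25+ site contrast the replicate block, with both groups alone, ended all gene calls, including Ifit1 (limma adjusted p = 0.280) and Ifih1 (adjusted p = 0.234). Ifih1 still differed by 1.35 there, and Ifit1 by at least 2.018. In lymph nodes same-numbered arrays of these 4 contrasts had lowest r of 0.0259, 0.0150, -0.00333 and 0.0283 and highest r of 0.323, 0.230, 0.419 and 0.508 across probe sets, and the same number was the best match in 1, 2, 3 and 1 of 3 pairs. The numbers may be labels only. Between CD25+ sites the same-numbered arrays also shared a run (1 and 2 in run D, 3 in run E). The 3 of 3 there may thus reflect runs as well as paired samples. With both groups fitted alone the peripheral count was 513 and the CD25+ site count 3, which was also 3 with log2(value + 16). Pancreas against lymph node gave 166 with the mesenteric contrast alone, 52 with the peripheral alone and 4 with the anti-ICOS contrast. Camera called 54 lists over all comparisons, and 8 with an estimated correlation. Of the 54 calls, 32 were lost without at least 1 array and 14 with the actin ratio as covariate. For anti-ICOS against IgG Treg cells, the macrophage and dendritic cell call turned its sign without IgG replicate 1 and was then not past the test (adjusted p = 0.258, and 1.00e-05 without IgG replicate 2). The means of 2 other called lists also crossed 0 and were then not past the test. They were exocrine markers in the interaction (0.00216 without anti-ICOS Treg replicate 2) and cytotoxic genes in the CD25+ site contrast (0.00722 without peripheral CD25+ replicate 3).

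Leaving out each array gave 450 (without Teff replicate 5) to 1000 for pancreatic IgG Treg against Teff, with 471 without Treg replicate 2. It gave 0 to 12 (without Treg replicate 3, also chosen as a doubted array) for anti-ICOS Treg against Teff, 0 to 35 (without IgG replicate 2) for anti-ICOS against IgG Treg, 0 to 1 (without IgG Treg replicate 1) for Teff and 0 throughout for the interaction. The mesenteric contrast gave 743 (without CD25- replicate 2; 798 without replicate 1) to 1878, and the peripheral 531 (without CD25+ replicate 2) to 1462 (without CD25+ replicate 1), with 546 and 597 without CD25- replicates 2 and 3. The site contrast gave 2 to 21 in CD25+ cells (without peripheral replicates 2 and 3; 5 without replicate 1) and 36 (without peripheral replicate 2) to 68 in CD25- cells. Pancreas against lymph node gave 160 (without Teff replicate 5) to 449 (without peripheral CD25+ replicate 1).

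Correlations of the contrasts across probe sets ranged, with an array left out, from 0.436 to 0.779 for both pancreatic treatments, 0.518 to 0.605 and 0.548 to 0.651 for pancreatic IgG with mesenteric and peripheral, and 0.752 to 0.886 between nodes. For anti-ICOS they ranged from 0.180 to 0.666 and from 0.179 to 0.737, lowest without Treg replicate 1.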

Other observations

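The test of the CD25 contrast between the sites and the fits with the actin ratio as covariate were chosen only after the results were seen, and the genes described were picked after their values were seen. Mesenteric CD25+ cells also carried more transcript of several genes of antigen presentation and B cells. The class II gene H2-Aa was 8.92 ± 0.45 (n = 5) against 6.63 ± 0.27 (n = 3) in CD25- cells, higher by 2.30 (SE 0.47, limma adjusted p = 0.00639), and H2-Eb1 by 1.84. Blk (1.59) and the invariant chain Cd74 (1.31) passed as well, though not without CD25- replicate 1 or 3, and Cd79b (1.07) and H2-Ab1 (1.03) did not pass without any 1 of the 3 CD25- arrays. With the actin 3'/5' ratio as covariate Cd74 (1.19) and Cd79b (1.04) did not pass (adjusted p = 0.0506 and 0.0716). Cd79a (0.06) and Cd22 (-0.10) did not pass. Of 16 B cell markers 6 rose and 1 fell (7 and 1 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.162). In peripheral nodes 1 of the 16 fell and none rose by limma (4 at an unadjusted p under 0.05), but the difference of the CD25 contrast between the sites passed for none of them.

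Ifng varied among the pancreatic arrays, with log2 values as deposited in each set. It lay at 10.11, 8.13 and 7.33 in anti-ICOS Treg cells, at 7.13, 6.41 and 6.26 in anti-ICOS Teff cells, from 5.37 to 7.17 in the IgG Treg arrays of both sets, and from 4.66 to 6.09 in IgG Teff cells. Lymph node arrays ranged from 2.54 to 2.94, near the 5th percentile of these arrays (log2 2.58 to 2.73). Tissue and set of records coincide, so these levels cannot be compared with those of the pancreas. The IgG Treg cells were sorted as CD69-, a gate not given for anti-ICOS Treg cells. By limma over all probe sets, Ifng did not pass for treatment in Treg cells (adjusted p = 0.893), in Teff cells (0.999) or as the interaction of treatment with cell type (adjusted p = 1), while in Treg cells it passed when adjusted over the cytokine or Th1 list alone.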
